A study of Homo sapiens with 8 samples.

How the data were processed

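Gene expression was measured with 8 dual-colour Agilent microarrays of human RNA. Per the labels, the Cy3 channel of each array held RNA of mock-transfected cells and the Cy5 channel held RNA of cells transfected with 1 miRNA by Lipofectamine RNAiMAX, extracted with Trizol. SBC cells, a lung cancer line, received the 5p or the 3p strand of miR-30a, miR-34b or miR-34c, and T24 cells, a bladder cancer line, the 5p or the 3p strand of miR-28. The strands come from the arms of 1 precursor each. Each miRNA had 1 array, no dye swap is recorded, and per the file headers all 8 arrays sat on 1 slide and were scanned on the same day. The series title speaks of siRNA whereas the labels name miRNAs, and the names of the labels were used.

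The deposited scanner files give spot and local background intensity in each channel, as median pixel values per the file headers. They also hold intensity values that Feature Extraction 12.1.1.1 had subtracted, detrended and dye-normalised, and its ratio as the log10 of Cy5 over Cy3. The deposited value table holds the same log10 ratio, with a largest difference of 0 from the scanner files on every array. The files have no column of mean signals, so the median signals took the place of the mean signals that had been planned.

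Each channel was background-corrected with the normexp method and an offset of 50, and each array was normalised with loess, in limma 3.58.1 under R 4.3.3. Control spots and spots marked as uneven by the scanner software were left out, spots of the same probe were averaged, and a gene was the mean of its probes that lay well above background in both channels. All values are log2 ratios of miRNA over mock unless stated. Raw signals were low, so the offset pulls ratios of dim probes toward 0. The standard deviation of log2 ratios over probes was 0.169 for miR-30a-5p here against 0.336 in the ratio of the scanner software, and Feature Extraction values are therefore given beside the lead genes. Every array has 62976 spots, of which 60901 are not controls, and 58201 probes. Probe names came from RefSeq accessions in the array files, matched to symbols in a table of the GRCh38.p14 assembly. That gave 31104 probes with 1 gene and 22439 symbols; 1976 probes with a RefSeq accession and 25121 with another kind of accession had no match. Genomic positions were used only to find the genes that host short RNAs, without regard to strand.

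Genes on a single array have no test and are described as lower or higher, with counts at a 2-fold threshold. Genes whose signal was below background in 1 channel only were given as bounds. For the miR-34 family, limma was fitted to the 6 SBC arrays with 1 coefficient for each arm, so that the miR-34b and miR-34c arrays of 1 arm served as a pair, with Benjamini-Hochberg adjusted p under 0.05 over 14365 genes measured on at least 2 arrays. This fit had 2 residual degrees of freedom and 2.84 prior ones. The spread it uses holds true differences between miR-34b and miR-34c, and its p-values measure only the spread between these arrays. On simulated data with 50 genes changed by 0.5 on the log2 scale, limma recovered 43, and it recovered all 50 at 1, 1.5 and 2, with 21 false calls over the same draw, more than the nominal share of calls.

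The 28 fixed gene lists covered reported miRNA targets (miR-34 5p, miR-30a-5p, miR-30a-3p, miR-28-5p), DNA replication and G1/S, mitosis, replication-dependent histones, p53 targets, interferon and RNA sensing, NF-kB and cytokines, cholesterol synthesis, fatty acid synthesis, unfolded protein and amino acid stress, hypoxia and glycolysis, extracellular matrix and adhesion, epithelial, mesenchymal, neuroendocrine, urothelial, leukocyte and fibroblast with endothelial markers, YAP and TGF-beta targets, RNA silencing machinery, ribosomal proteins, metallothioneins, apoptosis regulators, receptor tyrosine kinases with the RAS pathway, and autophagy with lysosome. They were written from general knowledge before the data were examined, as were the comparisons and the rule for named genes. On each array the median of a list was set against 10000 random lists of the same size matched on intensity in 20 bins, and a list among the lowest or highest 2.5% of these was called shifted. Checked on simulated data of 30 genes, 4% of unshifted lists fell outside, 66.5% of lists shifted by 0.1 and 100% of lists shifted by 0.25. The simulated genes were independent, so these rates do not cover lists whose genes vary together, which can fall outside more often. For the family fits, camera compared lists with all other genes, with its preset correlation and with an estimated one. The estimated form takes its degrees of freedom from the fit, here 2, so few lists could pass it at any correlation. An exact permutation test over the pairing of target lists with arrays asked whether lists were lower on their own array. Simulated tables passed it in 1 of 40 cases with no shift and 39 of 40 with a shift of 0.1. Correlations are across genes, which are not independent replicates, and carry no p-value.

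The rule for named genes took the 8 lowest and 8 highest genes of each array, the 3 lowest and 3 highest after subtraction of the median of the other arrays of the line, the 4 lowest reported targets of the transfected miRNA, the 3 most shifted members of each shifted list, and the 10 lowest and 10 highest genes of each family fit. The text names part of these genes, and some are not reported here. The planned test on seed sites in 3' UTRs was not run because no 3' UTR sequences were used here, and neither were its alternatives. The alternatives tried were no background correction, an offset of 16, median centring without loess, the Feature Extraction ratio, no filter on dim probes, the brighter part of the probes, the brightest probe, subtraction of the other arrays of the line, other limma settings, and each miR-34 array left out in turn. Protein-coding genes alone and the pairing test without each target list were added after the data were seen. List medians are given relative to the median of all genes of the array, and this form was set after the data were seen, as was the tolerance for a moved correlation, 1 over the root of the number of genes. Analyses outside R used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.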

Results

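The data were log2 ratios of miRNA-transfected over mock-transfected RNA on 8 arrays, 6 of SBC lung cancer cells and 2 of T24 bladder cancer cells, with 1 array per miRNA. Between 40.8% (miR-30a-3p) and 44.4% (miR-34c-5p) of the 58201 probes lay well above background in both channels of an array. The median signal of these probes above local background was 50 to 70.0 in the mock channel and 48.5 to 71.0 in the miRNA channel. Among 300 probes printed 10 times on each array, the median standard deviation between spots of 1 probe was 0.0457 to 0.0521 on the log2 scale. Because each miRNA had a single array, the values below for single arrays have no test, and the number of arrays limits their precision. The comparisons ask which transcripts differed after transfection of each strand.

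The mock channels served as the background of these comparisons. Between SBC arrays of different miRNA genes, gene levels in the mock channels differed with a standard deviation of 0.0970 to 0.207 over 12259 genes, and 0 to 17 genes differed at least 2-fold. Between arrays of 1 miRNA gene that deviation was 0.0632 to 0.0694, with 0 to 1 genes at 2-fold. Of the 15 ways to pair the SBC arrays, the pairing by miRNA gene had the lowest mean deviation (exact permutation p = 0.0667, the smallest this design can give). Over the same genes the log2 ratios had a standard deviation of 0.303 for miR-34b-5p and 0.336 for miR-34c-5p, above the highest mock value for either array (0.176 and 0.207). The other SBC arrays were near or below the highest mock value of their array, with 0.178 for miR-30a-5p (mock 0.206), 0.177 for miR-30a-3p (0.207), 0.181 for miR-34b-3p (0.180) and 0.124 for miR-34c-3p (0.202). Those high mock values came from miR-30a against miR-34 arrays (0.174 to 0.207). Mock channels of miR-34b against miR-34c differed by 0.0970 to 0.107, with 0 to 1 genes at 2-fold. Both miR-34 3p arrays lay above that narrower spread, though ratios, unlike differences of mock channels, also hold dye bias.

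**Figure D1:**
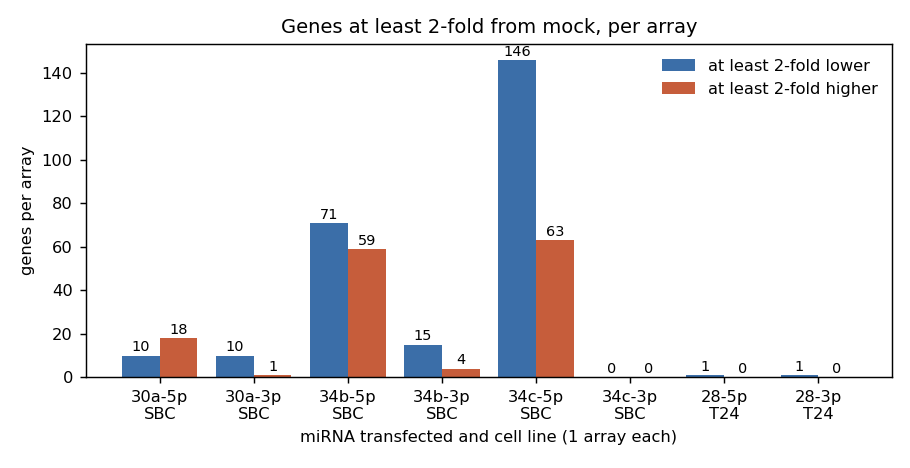
Bars show the number of genes at least 2-fold lower (blue) or higher (red) than mock on each array, for each miRNA and cell line (1 array each). The 34c-5p array had 146 lower and 63 higher genes and the 34b-5p array 71 and 59, against at most 18 in either direction on the others.

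After miR-30a-5p, SBC cells had lower levels of several reported targets and higher levels of chemokine, protein-folding stress and metallothionein genes. GNAI2, an inhibitory G protein subunit, was lower by log2 -1.23 (Feature Extraction -1.27) and SEC23A, a coat protein of vesicles leaving the endoplasmic reticulum, by -1.05 (Feature Extraction -1.56). The mesenchymal filament gene VIM was at -0.85 and the mTORC1 inhibitor DDIT4 at -0.80. Neither fall was particular to this strand. On the other SBC arrays VIM ranged from -0.91 after miR-30a-3p to 0.27 after miR-34c-3p, and DDIT4 from -0.74 to -0.21. Of 34 measured reported miR-30a-5p targets, 8 were lower and 0 higher by at least 0.5, and the list median was -0.09 relative to all genes. The neuropeptide gene TAC3 was highest at 1.59 (Feature Extraction 1.81), and UTS2, which encodes urotensin, was at 1.45. The imprinted noncoding RNA H19 was higher by 1.43. The largest decreases were RN7SL1, the RNA of the signal recognition particle, at -1.69, and BEX1 at -1.66.

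The NF-kB and cytokine list was higher after miR-30a-5p, with a median of 0.42 and 6 of 14 genes up by at least 0.5, among them the neutrophil chemokines CXCL3 (1.27), CXCL2 (1.12) and CXCL8 (0.93). In the unfolded protein and amino acid stress list, 9 of 25 genes were higher and 1 lower by 0.5, with a median of 0.35. HSPA5, the main chaperone of the endoplasmic reticulum, was at 1.28, HERPUD1 at 1.19 and the mitochondrial folate enzyme MTHFD2 at 0.91. Metallothioneins, which bind metal ions, had a median of 0.54, with MT2A at 0.91 and MT1B at 0.57. Reported targets of the sister strand miR-30a-3p were higher, with a median of 0.32 and CCN1 at 0.82. Smaller shifts were DNA replication and G1/S at 0.16 (E2F2 0.97), miR-34 5p targets at 0.05, p53 targets at -0.09 and fatty acid synthesis at -0.20. Those of DNA replication and G1/S and of p53 targets were near-equal after miR-30a-3p and not particular to this strand. Of 13777 genes, 10 were at least 2-fold lower and 18 higher, 28 in all. Over the 12259 genes of the mock comparison there were 20, against 15 to 17 between the mock channel of this array and those of other miRNA genes. The counts were 91 and 88 with the Feature Extraction ratio and 44 in all without background correction.

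After miR-30a-3p, SBC cells had lower levels of EPAS1, which encodes the hypoxia factor HIF-2alpha, at -0.55, of CCN1 at -0.50 and of CDK6 at -0.34, all reported targets of this strand. The 6 measured targets had a median of -0.24, against 0.32 on the miR-30a-5p array. TAC3 was lower by -1.30 (Feature Extraction -1.77), the opposite of the miR-30a-5p array. The adenosine deaminase gene ADA was at -1.29 (Feature Extraction -1.42), the adhesion gene CEACAM1 at -1.19, and RN7SL1 at -1.47. The highest genes were CXCL8 at 1.04, PCOLCE, an enhancer of procollagen processing, at 0.96, and CHAC1, a glutathione-degrading enzyme, at 0.95.

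Replication-dependent histones were higher after miR-30a-3p, with a median of 0.36 over 11 genes and H1-2 at 0.53, and so was DNA replication and G1/S at 0.16. The mesenchymal list was lower at -0.16 (VIM -0.91, SPARC -0.56), as were YAP and TGF-beta targets at -0.17 (AJUBA -0.83) and metallothioneins at -0.28 (MT2A -0.53). Lower medians also held for p53 targets (-0.09), interferon and RNA sensing (-0.07) and receptor tyrosine kinases (-0.07, DUSP6 -0.77). DNA replication and G1/S and p53 targets had the same medians, 0.16 and -0.09, after miR-30a-5p. The 2 miR-30a arrays had near-equal mock channels, and list shifts between mock channels were not measured. For these lists a shared mock and an effect of either strand cannot be told apart. NF-kB and cytokines had 0.15 and hypoxia and glycolysis -0.15, and both signs turned when the other SBC arrays were subtracted. Urothelial markers had -0.12, which turned to 6.52e-04 without the filter on dim probes. Of 13502 genes, 10 were at least 2-fold lower and 1 higher. Over the 12259 genes of the mock comparison there were 10, fewer than the 12 to 14 between the mock channel of this array and those of other miRNA genes. The Feature Extraction ratio gave 166 and 29, an offset of 16 gave 38 in all, no background correction 39, and subtraction of the other SBC arrays 29.

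After miR-34b-5p, cell cycle genes were lower and p53 target genes higher in SBC cells. CDK4, the G1 kinase and a reported target, was 4.18-fold lower at log2 -2.06 (Feature Extraction -2.14). MCM3, a subunit of the replicative helicase, was at -1.57, the ubiquitin ligase adaptor DTL at -1.66 and the nucleoporin NDC1 at -1.74. Of 41 DNA replication and G1/S genes, 25 were lower by at least 0.5 and 0 higher, with a median of -0.61. Of 27 p53 targets, 19 were higher and 1 lower, with a median of 0.64, including the mitochondrial reductase FDXR (1.60), PHLDA3 (1.22) and the pro-apoptotic BBC3 (1.07). The highest genes were short nuclear RNAs of the H/ACA and Cajal body classes, which guide modification of other RNAs, such as SCARNA11 at 2.30 (Feature Extraction 3.33), SNORA80E at 2.30 and SNORA48 at 2.17.

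Mitosis genes had a median of -0.32 (BUB1B -0.88), replication-dependent histones -0.31 (H3C4 -0.86), and hypoxia and glycolysis -0.28 with the hypoxia marker CA9 at -1.50 and NDRG1 at -1.69. The reported miR-34 5p targets had -0.17, with 10 of 35 lower by 0.5, among them E2F5 (-1.16) and MYC (-0.86), and 1 higher, CCND1 (0.58). Autophagy and lysosome genes had 0.29 (SQSTM1 0.84, CTSD 0.84), interferon and RNA sensing 0.26 (ISG15 1.14), YAP and TGF-beta targets 0.15 (ID2 0.81), extracellular matrix 0.14 (TIMP2 1.17; 6 genes higher and 3 lower by 0.5) and receptor tyrosine kinases 0.10 (IGF2R 0.75; 4 higher and 1 lower). Unfolded protein and amino acid stress had -0.11, with 5 genes lower and 2 higher by 0.5 and the serine synthesis enzyme PHGDH at -1.52, neuroendocrine markers -0.28 (STMN1 -0.64), and the miR-30a-5p targets -0.10. Of 14082 genes, 71 were at least 2-fold lower and 59 higher, median centring gave 59 and 71, and protein-coding genes alone gave 67 and 27. The Feature Extraction ratio gave 375 and 288, no background correction 248 in all and an offset of 16 240.

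After miR-34c-5p, replication, histone and mitosis genes were lower and p53 target genes higher in SBC cells. The thymidine kinase gene TK1 was 6.12-fold lower at -2.62 (Feature Extraction -2.71), CDK4 was at -2.07, PCLAF, a partner of the replication clamp, at -2.02, and MCM3 at -1.91. DNA replication and G1/S had a median of -0.77 with 31 of 41 genes lower by 0.5 and 0 higher. Histones had -0.79 with H3C4 at -1.68, and mitosis -0.51 with SPC25 at -1.66. The reported targets had a median of -0.25, with 13 of 35 lower, including the lactate dehydrogenase gene LDHA (-1.45), E2F5 (-1.28) and the phosphatase gene CDC25A (-1.21). SPEF1, a gene of cilia and sperm tails, was highest at 2.43 (Feature Extraction 3.00), ahead of SCARNA11 at 2.08, and CDKN1C, which encodes the cell cycle inhibitor p57, was at 1.86.

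The p53 targets had a median of 0.38 after miR-34c-5p with 7 of 27 higher by 0.5 (PLK3 1.09, TNFRSF10B 0.92). YAP and TGF-beta targets had 0.32 (ID2 0.99), interferon and RNA sensing 0.18 (ISG15 1.33) and autophagy and lysosome 0.14 (ATG4A 0.61). NF-kB and cytokines had 0.15 (RELB 0.65), which turned to -0.06 when the other SBC arrays were subtracted. Fatty acid synthesis had -0.27 (FADS1 -1.01), cholesterol synthesis -0.15, hypoxia and glycolysis -0.18 (NDRG1 -1.56), miR-30a-5p targets -0.11 (DTL -1.53; 9 genes lower and 2 higher by 0.5), and the 4 measured fibroblast and endothelial markers -0.18 (COL1A1 -0.59). Of 14157 genes, 146 were at least 2-fold lower and 63 higher, median centring turned that split to 89 and 114, and protein-coding genes alone gave 146 and 34. The Feature Extraction ratio gave 526 and 347, no background correction 381 in all and an offset of 16 373.

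After miR-34b-3p, 5 of the 8 lowest genes in SBC cells were short nuclear RNAs. SNORA67 was at -1.72 (Feature Extraction -2.09), SCARNA22 at -1.62 and SCARNA20 at -1.53, of which SNORA67 and SCARNA20 were higher on the miR-34b-5p array (1.80 and 2.17). NDRG1, a gene induced by low oxygen, was at -1.40 and the survivin gene BIRC5 at -1.10. The transcription factor KLF2 was at 1.57 (Feature Extraction 2.56), RN7SL1 at 1.32, TXNIP, an inhibitor of thioredoxin, at 1.24 and KLF6 at 1.04. DNA replication and G1/S had a median of -0.22 (MCM4 -0.56), mitosis -0.18 and hypoxia and glycolysis -0.10 (CA9 -0.73). Ribosomal proteins had 0.19 (RPLP1 0.39), metallothioneins 0.18 (MT1F 0.54), NF-kB and cytokines 0.14 (CXCL1 0.59) and urothelial markers -0.11. Epithelial markers had -0.12 (CLDN7 -0.34) and turned to 0.01 when the other SBC arrays were subtracted. Of 14165 genes, 15 were at least 2-fold lower and 4 higher. Over the 12259 genes of the mock comparison there were 17. The mock channel of this array gave 0 to 1 against those of miR-34c and 14 to 17 against those of miR-30a. Median centring gave 8 and 7, the Feature Extraction ratio 150 and 28. No background correction gave 43 in all, an offset of 16 gave 42, and subtraction of the other SBC arrays or protein-coding genes alone gave 12.

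After miR-34c-3p no gene of 14156 was 2-fold lower or higher in SBC cells. The lowest were RNF11, an endocytic ubiquitin ligase, at -0.93 (Feature Extraction -1.07), the complex I gene NDUFA5 at -0.92, the lysosomal membrane gene SCARB2 at -0.91 and the actin-capping gene CAPZA1 at -0.85. The highest were the short noncoding RNA SNAR-A3 and the neuropeptide precursor VGF, both at 0.93. Ribosomal proteins had a median of 0.08 (RPL6 0.23), neuroendocrine markers 0.16 (CHGA 0.55), fatty acid synthesis 0.11 (SCD 0.23), RNA silencing machinery 0.10 (TNRC6C 0.41), and interferon and RNA sensing -0.10 (STAT2 -0.32). DNA replication and G1/S (-0.07) and unfolded protein and amino acid stress (-0.09) changed sign with median centring and when the other SBC arrays were subtracted. Median centring, which moved the median of all genes by 0.109 on this array, gave 0 lower and 7 higher genes. The Feature Extraction ratio gave 18 and 7, subtraction of the other SBC arrays 6 in all, no background correction or an offset of 16 gave 2, and the brightest probe 1. Over the 12259 genes of the mock comparison, which average fewer probes, there was 1 gene at 2-fold. The mock channel of this array gave 0 to 1 against those of miR-34b and 12 to 15 against those of miR-30a.

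After miR-28-5p the T24 cells had few differences from mock. CTSZ, a lysosomal protease gene, was at -0.63 (Feature Extraction -0.76), the motor protein gene KIF13A at -0.61 (Feature Extraction -2.14) and the ribosomal RNA gene RNA18SN5 at -0.53, and the highest gene, the lysosomal transporter SLC66A1, was at 0.49. The reported miR-28-5p targets had a median of -0.06 over 12 genes, with MAD2L1 of the spindle checkpoint at -0.18 and RAB23 at -0.16, and this turned to 0.0018 against the other T24 array. Mitosis genes had -0.07 (KIF11 -0.22), YAP and TGF-beta targets -0.06 (ID1 -0.34), receptor tyrosine kinases -0.04, interferon and RNA sensing -0.03, metallothioneins 0.09 (MT2A 0.25), histones 0.08 (H2BC4 0.28) and hypoxia and glycolysis 0.06 (ANKRD37 0.33). Ribosomal proteins had 0.07 (RPS20 0.28), which turned to -0.0077 with the Feature Extraction ratio. Of 13888 genes 1 was at least 2-fold lower and 0 higher. That gene was MIR19A, a miRNA precursor, at -5.10, whose single probe read 11.5 in the mock channel here and 5.75 in the mock channel of the other T24 array. MYO1G, below background in the miRNA channel, was at least 2.89-fold lower, a bound that rests on 1 mock channel: its mock signal was 7.34 here and 5.78 on the other T24 array, near the floor of 5.81. The count was 8 with the Feature Extraction ratio, 2 without background correction, with an offset of 16, without the filter or with brighter probes alone, and 0 for protein-coding genes or against the other T24 array.

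After miR-28-3p, CTSZ was the only one of 13925 genes at least 2-fold from mock, at -1.19 (Feature Extraction -1.74). RN7SL1 was at -0.94 and RNA18SN5 at -0.54. The highest genes were SLC66A1 at 0.54 and the tyrosine kinase gene PTK6 at 0.51. Ribosomal proteins had a median of 0.10 (RPS20 0.29), histones 0.07 (H2BC11 0.20) and receptor tyrosine kinases -0.04 (PIK3R1 -0.15), and each sign turned when the miR-28-5p array was subtracted. DNA replication and G1/S had 0.05 (TYMS 0.20) and fatty acid synthesis -0.10 (ME1 -0.15). The Feature Extraction ratio gave 6 genes at 2-fold, and subtraction of the other T24 array gave 0. Between the miR-28-5p and miR-28-3p arrays 0 of 13708 genes differed at least 2-fold.

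**Figure D2:**
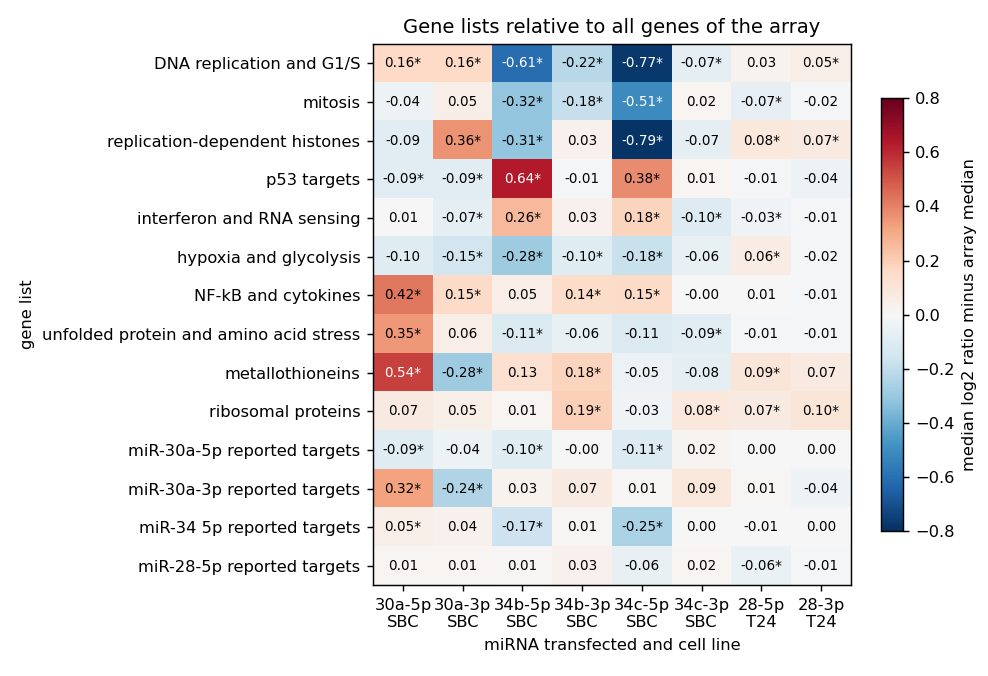
Colours and numbers show the median log2 ratio of each gene list relative to all genes of the array, for 14 of the 28 lists and 8 arrays. Stars mark medians among the lowest or highest 2.5% of random lists, with DNA replication and G1/S at -0.61 after miR-34b-5p and -0.77 after miR-34c-5p.

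Across the 224 combinations of list and array, 78 were shifted, against 11.2 by chance for lists of unrelated genes. Genes of 1 list can vary together, with estimated correlations in the SBC fit of 0.707 for mitosis, 0.838 for metallothioneins and -0.099 for epithelial markers. The value of 11.2 is therefore too low a standard for lists such as the first 2. Shifted lists were most frequent after miR-34b-5p and miR-34c-5p, with 14 of 28 each, and least after miR-28-3p, with 5. Leukocyte markers and apoptosis regulators were shifted on 0 arrays. On no array did the median and the mean of a shifted list differ in sign. Of the 78, 40 stayed shifted with 1 sign under all 4 other settings (median centring, the Feature Extraction ratio, no filter and subtraction of the other arrays of the line). At least 1 of these settings ended or turned the shift of fatty acid synthesis after miR-30a-5p, and after miR-30a-3p those of p53 targets, interferon and RNA sensing, NF-kB, hypoxia and urothelial markers. The same held after miR-34b-5p for miR-30a-5p targets, unfolded protein stress, hypoxia, YAP and TGF-beta targets and receptor tyrosine kinases, and after miR-34b-3p for NF-kB, hypoxia, epithelial and urothelial markers. It held after miR-34c-5p for miR-30a-5p targets, NF-kB, hypoxia, fibroblast and endothelial markers, and autophagy and lysosome. After miR-34c-3p it held for all 7 shifted lists, after miR-28-5p for all but mitosis and hypoxia, and after miR-28-3p for all but DNA replication and G1/S.

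The reported targets of a miRNA were lower on the array of that miRNA than on the others, though for miR-28-5p by very little. On other arrays the miR-28-5p list ran from -0.04 (SBC miR-34c-5p) to 0.11 (SBC miR-34b-5p), with -0.02 on the T24 miR-28-3p array. The mean shift was -0.26 for miR-30a-5p, -0.22 for miR-30a-3p, -0.26 for miR-34b-5p, -0.42 for miR-34c-5p and -0.04 for miR-28-5p, relative to all genes. Over these 5 own arrays it averaged -0.21, against -0.03 over 6720 pairings of lists with arrays. The exact permutation test was one-sided with p = 2.98e-04, the smallest it can give. No target list was fixed for miR-34b-3p, miR-34c-3p or miR-28-3p.

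When miR-34b-5p and miR-34c-5p were taken as a pair in limma, 1303 genes fell and 1144 rose against mock, 2447 of 14365 genes. CDK4 fell by 2.07 on the log2 scale (standard error 0.055, adjusted p = 0.00521), 4.19-fold and lower on 2 of 2 arrays. MCM3 fell by 1.74, NDC1 by 1.71 and DTL by 1.60, with adjusted p from 0.00745 to 0.0101, each lower on 2 of 2 arrays. TK1 fell by 1.81 (standard error 0.368, adjusted p = 0.0368), BEX1 by 1.94, the hypoxia-induced NDRG1 by 1.62, DISP2 by 1.52 and the linker histone H1-5 by 1.42, again on both arrays. The NDRG1 fall was not particular to the 5p arms, with -1.40 after miR-34b-3p and -0.66 after miR-34c-3p. BEX1 was also at -1.66 after miR-30a-5p, but at 0.19 after miR-30a-3p, -0.25 after miR-34b-3p and 0.56 after miR-34c-3p. SCARNA11 rose by 2.19 (standard error 0.079, adjusted p = 0.00745), 4.55-fold and higher on 2 of 2 arrays. SNORA80E (2.11), SNORA48 (2.09), SNORA67 (1.88), SNORA63 (1.84), SNORA2B (1.84), SNORA80A (1.83), SCARNA20 (1.80) and SCARNA13 (1.72) also rose, and the cell cycle inhibitor CDKN1C rose by 1.63 (adjusted p = 0.0105), higher on 2 of 2 arrays. Over the same pair of arrays the whole classes had medians of 0.22 for 92 SNORA genes, 0.46 for 20 SCARNA genes and -0.02 for 119 SNORD genes, with 15, 7 and 0 genes at least 2-fold higher on both arrays.

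Of 41 DNA replication and G1/S genes, 36 fell, 0 rose and 5 did not pass in the miR-34 5p pair, and 36 fell when adjusted over the list alone (median -0.67, camera adjusted p = 1.12e-19). Mitosis had 23 of 45 lower and 22 not passed (31 adjusted over the list alone, median -0.42, camera adjusted p = 9.02e-14), and histones 8 of 11 lower (10 adjusted over the list alone, median -0.62, camera adjusted p = 1.06e-05). Of 27 p53 targets, 16 rose, 1 fell and 10 did not pass (21 rose adjusted over the list alone, median 0.50, camera adjusted p = 5.3e-09). The reported miR-34 5p targets had 14 fallen, 1 risen and 20 not passed of 35 (16 fell adjusted over the list alone, median -0.14, camera adjusted p = 1.06e-05). Hypoxia and glycolysis had 8 of 23 lower (9 adjusted over the list alone, median -0.27, camera adjusted p = 2.06e-05), and interferon and RNA sensing 10 of 26 higher (10 adjusted over the list alone, median 0.20, camera adjusted p = 4.22e-04). Autophagy and lysosome had 6 risen and 1 fallen of 23 (median 0.18, camera adjusted p = 0.00192). Fatty acid synthesis (5 of 11 lower, 1 higher, median -0.14), YAP and TGF-beta targets (4 of 12 higher, median 0.17) and neuroendocrine markers (1 of 6 lower, median -0.22) had camera adjusted p of 0.041, 0.0416 and 0.041. None of these 11 list calls held with an estimated correlation, where the lowest adjusted p was 0.513. That form rests on 2 residual degrees of freedom, so few lists could pass it. The estimated correlation was 0.551 for DNA replication and G1/S, 0.707 for mitosis and 0.67 for histones. It was 0.278 for p53 targets, 0.093 for miR-34 5p targets and 0.053 for interferon and RNA sensing. The preset form uses 1 fixed correlation for every list, so its p-values do not reflect these values. Correlation within a list may account for the calls with high values, which these data cannot settle.

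The other 17 lists did not pass camera in the miR-34 5p pair. For 4 of them median, mean and test differed in sign, with a lowest adjusted p of 0.868. Gene-specific dye bias is part of these ratios, as there was no dye swap. Median centring gave 457 lower and 1148 higher genes, 1605 in all, and the fit without the filter gave 1615.

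**Figure D3:**
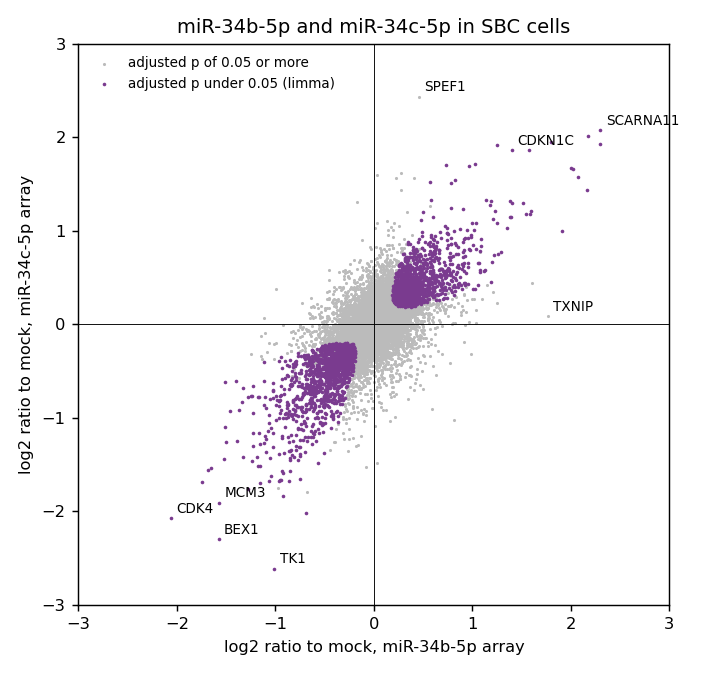
Each point is a gene, with its log2 ratio to mock on the miR-34b-5p array (x axis) and the miR-34c-5p array (y axis), in purple where limma gave an adjusted p under 0.05 (2447 genes). CDK4 lies at -2.06 and -2.07 and SCARNA11 at 2.30 and 2.08, while SPEF1 (0.45 and 2.43) and TXNIP (1.77 and 0.09) lie off the diagonal.

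The miR-34b-3p and miR-34c-3p pair had 0 genes past an adjusted p of 0.05 in limma, with 1358 genes at an unadjusted p under 0.05. SCARB2 was at -0.89, the actin-capping gene CAPZA1 at -0.73 and ANGPTL4, an inhibitor of lipoprotein lipase, at -0.60, while the receptor TGFBR2 was at 0.66 and the ceramidase ASAH1 at 0.58. The lowest adjusted p was 0.415, for SCARB2, lower on 2 of 2 arrays. Of 34 ribosomal protein genes, 0 passed and all 34 were higher (median 0.13, camera adjusted p = 4.19e-11). That shift was not particular to this pair. Relative to all genes the list was at 0.070 and 0.095 on the T24 arrays and 0.072 after miR-30a-5p, against 0.013 after miR-34b-5p and -0.030 after miR-34c-5p. Of 41 DNA replication and G1/S genes 0 passed and 34 were lower (median -0.15, camera adjusted p = 7.33e-07). Camera also passed hypoxia and glycolysis (median -0.08, adjusted p = 1.36e-04), RNA silencing machinery (0.11, adjusted p = 8.80e-04), mitosis (-0.09, adjusted p = 0.00246), unfolded protein and amino acid stress (-0.06, adjusted p = 0.034) and epithelial markers (-0.06, adjusted p = 0.034). With an estimated correlation none of these 7 calls held, the lowest adjusted p being 0.787. This loss decides little on its own, as that form rests on 2 residual degrees of freedom. The estimated correlation was 0.328 for ribosomal proteins, 0.551 for DNA replication and G1/S and 0.707 for mitosis. Their unadjusted camera p with it was 0.141, 0.311 and 0.534, so correlation within these lists may account for their calls. RNA silencing machinery, with an estimated correlation of -0.026, went from an unadjusted camera p of 1.26e-04 to 0.0557. For 8 other lists median, mean and test differed in sign, with a lowest adjusted p of 0.911.

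The difference between the 5p pair and the 3p pair, in which a gene-specific dye bias cancels, had 27 lower and 23 higher genes in limma, 50 in all. CDK4 was lower by -1.96 (standard error 0.077, adjusted p = 0.0361), NDC1 by -1.62, the pentose phosphate enzyme RPIA by -1.62, MCM3 by -1.59 and the sodium pump subunit ATP1B3 by -1.57. SNORA80E was higher by 2.61, SNORA48 by 2.39, SCARNA11 by 2.36 (adjusted p = 0.0411), SNORA2B by 2.22 and CDKN1C by 1.96 (adjusted p = 0.0446), and each of these differences had 1 sign for miR-34b and miR-34c. The call did not last under most other settings: limma gave 0 genes with median centring, the Feature Extraction ratio, no filter, miR-34b and miR-34c as blocks, trend with robust fitting, or without either 3p array. At an unadjusted p under 0.05 it had 3096 genes as first run and 1514 to 3691 in those fits. No background correction gave 369 genes, and leaving out miR-34b-5p or miR-34c-5p gave 1685 or 966.

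In the same difference, DNA replication and G1/S had 1 gene lower of 41 over all genes and 30 adjusted over the list alone (median -0.49, camera adjusted p = 3.53e-16). The p53 targets had 0 of 27 past over all genes and 17 higher adjusted over the list alone (median 0.57, camera adjusted p = 7.47e-10). Reported miR-34 5p targets had 4 of 35 lower over all genes and 14 adjusted over the list alone (median -0.21, camera adjusted p = 3.10e-06). Camera also passed mitosis (median -0.28, adjusted p = 4.23e-10), histones (-0.55, adjusted p = 3.78e-06), ribosomal proteins (-0.15, adjusted p = 1.55e-04), interferon and RNA sensing (0.19, adjusted p = 2.09e-04) and autophagy and lysosome (0.22, adjusted p = 0.00111), but over all genes 0 of their 45, 11, 34, 26 and 23 genes passed. Adjusted over the list alone, mitosis had 3 genes lower, histones 8 lower, ribosomal proteins 2 lower and 1 higher, interferon and RNA sensing 1 lower and 8 higher, and autophagy and lysosome 1 lower and 2 higher. Camera passed 13 lists in all, and none held with an estimated correlation, where the lowest adjusted p was 0.563. With 2 residual degrees of freedom, that form cannot decide on the calls here, and the correlations estimated within lists are the same as above. Those of DNA replication and G1/S (0.551), mitosis (0.707) and histones (0.67) may account for the calls of these lists. For 4 lists median, mean and test differed in sign, with a lowest adjusted p of 0.89.

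Between single arrays, SBC cells with miR-34c-5p had 34 genes at least 2-fold lower and 15 higher than those with miR-34b-5p. UTS2 (-1.84), TXNIP (-1.68) and TK1 (-1.60) were lower, and SPEF1 (1.98), the natriuretic peptide gene NPPB (1.56) and RSPH1 of ciliary radial spokes (1.34) were higher. Of the 2-fold genes in the 13843 measured on both arrays, 34 were lower on both (70 and 145 on each, 0.733 by independence) and 30 higher on both (59 and 63, 0.269 by independence). Between miR-34c-3p and miR-34b-3p, 3 genes were lower (RN7SL1 -1.76, KLF2 -1.54, KLF6 -1.01) and 8 higher, VGF by 1.96. Between the arms of 1 gene, 14 genes were lower and 40 higher for miR-30a-5p over miR-30a-3p (BEX1 -1.85, TAC3 2.88), 48 and 84 for miR-34b (CDK4 -1.90, SCARNA20 3.70), and 158 and 77 for miR-34c (BEX1 -2.86, SPEF1 2.41). These differences have no test.

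Log2 ratios across 12269 genes correlated most between miR-34b-5p and miR-34c-5p, with Pearson's r of 0.690 (Spearman 0.619, covariance 0.0689). The T24 pair had 0.653 and the pair of miR-34b-3p and miR-34c-3p 0.474. Arms of 1 gene in SBC cells had 0.291 for miR-30a, 0.268 for miR-34b and 0.108 for miR-34c. Arrays of 1 miRNA gene had near-equal mock channels. A pair simulated with the mean mock spread of the SBC arrays, which shared its mock and nothing else, had r of 0.418 and a covariance of 0.0116. The measured covariances were 0.0090 for miR-30a, 0.0044 for miR-34c and 0.0144 for miR-34b. That mean spread mixes miR-30a against miR-34 mocks (standard deviation 0.174 to 0.207) with miR-34b against miR-34c mocks (0.0970 to 0.107). It is too wide for the miR-34 arrays, so the simulation decides nothing for them. The T24 pair was not set against the simulation. The 12 pairs of an SBC and a T24 array, which share neither RNA nor cell line, had 0.072 to 0.308 with a mean of 0.195.

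**Figure D4:**
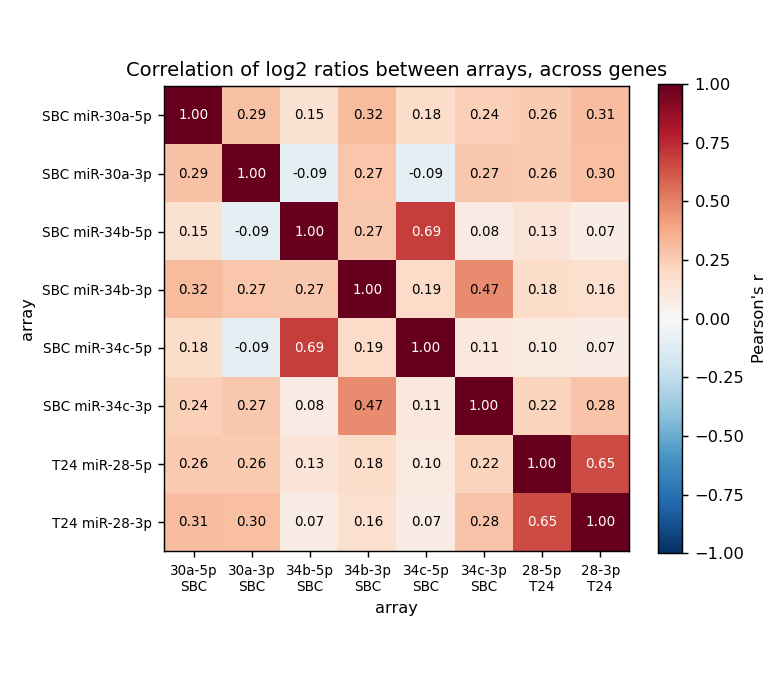
Pearson's r of log2 ratios across 12269 genes for each pair of the 8 arrays. The pair of miR-34b-5p and miR-34c-5p has 0.690, and pairs of an SBC and a T24 array have 0.072 to 0.308.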

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

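Both tests on short nuclear RNAs, the tests on the sign of a second probe, the correlation in genes with 1 probe and the spike-in test were chosen after the results were seen. Probes without a gene name differed from mock more often than mock channels differed from each other on 3 arrays. At least 2-fold differences from mock were shown by 7 of 6397 such probes after miR-30a-5p, 9 of 6949 after miR-34b-5p and 26 of 7182 after miR-34c-5p. Between the mock channels of these arrays and others of the line there were at most 5, 1 and 4. These shares are below those of named genes on the same arrays (0.203%, 0.923% and 1.48%). The unnamed probes have no test and no name here.

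The first pattern was the higher level of short nuclear RNAs in both miR-34 5p arrays, where 22 H/ACA and Cajal body RNA genes were at least 2-fold higher on both, out of 112 measured, whose median log2 was 0.296, so most of the class did not reach 2-fold. A higher yield of short RNAs of every class in the transfected RNA is argued against by the C/D box class, whose 119 SNORD genes had a median of -0.0234, lower than that of the 112 genes by 0.320 (bootstrap standard error 0.060), with 0 at 2-fold on both. Higher levels of the host genes of the 22 are argued against by a host median of -0.0925 over 18 hosts (standard deviation 0.274), of which 10 were lower on both arrays; hosts were found by position without regard to strand. A yield or labelling difference of this 1 class stays open, as SNORA67 and SCARNA20 were lower on the miR-34b-3p array, and so does an effect of miR-34 5p, which the design names and which was not tested against it.

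The next pattern was that 970 of 12269 genes, 7.91%, had 1 sign on all 8 arrays, against 4.54% if the lines were independent and arrays within a line were as alike as measured, of which 24 reached 0.2 on all arrays and 0 reached 0.5. In genes with several probes (223 of the 970), a response to transfection shared by both cell lines, or a dye bias shared by all probes of a gene, is argued against as the whole cause: in 335 genes whose first probe had 1 sign on all 6 SBC arrays, that probe kept the sign in T24 in 74.9%, 23.3 points (standard error 3.68) more than a second probe of the same gene, which shared the sign in SBC in 79.4%. Dye bias that differs from probe to probe may be the cause there, as the second probe had the sign in T24 in 51.6%, against 50% by chance, and in 42.8% to 53.3% over 200 other draws of the probes; probes that read different transcripts of a gene were not tested. A correlation of 0.428 between probes over 2926 genes, the test chosen beforehand, decides nothing, because its mean over 8 arrays holds the miR-34 5p response, for which the correlation was 0.684. In genes with 1 probe, where the mean correlation between arrays of different lines was 0.199, dye and transfection cannot be told apart without a dye swap.

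The last pattern was the small number of differences in T24 cells, with 1 gene at 2-fold on each array. A weaker response of these arrays to known ratios is argued against by their spike-in slopes, the lower of which was 0.844, not below the highest slope of the SBC arrays (0.841). Lower delivery of the miRNA and a weaker effect of miR-28 in these cells stay open, and neither was tested. The MIR19A value of -5.10 rests on 1 probe that was bright in 1 mock channel.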

How the results depend on the processing

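All alternatives were planned except protein-coding genes alone and the target lists left out in turn, which were added after the data were seen. Low signal over background limited the counts, as background correction and its offset set how far ratios of dim probes move. The cause was not tested for any change below unless the setting itself gives it, such as fewer genes. The test on seed sites and its alternatives were not run.

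Genes at least 2-fold changed numbered 28 after miR-30a-5p, 11 after miR-30a-3p, 130 after miR-34b-5p, 19 after miR-34b-3p, 209 after miR-34c-5p, 0 after miR-34c-3p and 1 on each T24 array. In that order, the Feature Extraction ratio and the identical deposited table gave 179, 195, 663, 178, 873, 25, 8 and 6. No background correction gave 44, 39, 248, 43, 381 and 2 in SBC cells and 2 after miR-28-5p. An offset of 16 gave 38 after miR-30a-3p, 240 after miR-34b-5p, 42 after miR-34b-3p, 373 after miR-34c-5p, 2 after miR-34c-3p and 2 after miR-28-5p. Subtraction of the other arrays of the line gave 29 after miR-30a-3p, 12 after miR-34b-3p, 6 after miR-34c-3p and 0 on both T24 arrays. Median centring gave 7 and the brightest probe 1 after miR-34c-3p. Protein-coding genes alone gave 12 after miR-34b-3p and 0 after miR-28-5p, and no filter or brighter probes alone gave 2 after miR-28-5p. The correlation of miR-34b-5p with miR-34c-5p was 0.655 with the Feature Extraction ratio, 0.707 for brighter genes and 0.619 by rank.

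In limma, the 5p pair had 2447 genes, and 1605 with median centring and 1615 without the filter, of which 1404 and 1503 were among the 2447. The fit shares its spread between both pairs, and the standard deviation of miR-34b minus miR-34c was 0.242 for the 5p arms and 0.158 for the 3p arms. With 1 array of the 5p pair left out, the spread comes from the 3p pair alone, so counts from those fits show nothing on stability. The 4 miR-34 arrays alone gave the identical fit, since the miR-30a arrays add no residual degrees of freedom, and this shows nothing on stability. The 3p pair had 0 genes in all fits that kept both of its arrays, with 1042 to 2801 at an unadjusted p under 0.05. The difference had 50 genes, 369 without background correction and 0 with median centring, the Feature Extraction ratio, no filter, miR-34b and miR-34c as blocks, or trend with robust fitting. It ranged from 0 (without miR-34b-3p or miR-34c-3p) to 1685 (without miR-34b-5p; 966 without miR-34c-5p), where the lone array is assumed to vary like the others. Without that identical fit, the 20 genes called in the 5p pair among those chosen for naming had 140 values under other settings, of which 134 still passed, 6 no longer passed and 0 turned sign. The 20 of the difference had 200 values, of which 60 still passed and 140 no longer did. Both sets of values include fits with 1 array left out, which leave 1 array in an arm.

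The target lists kept their shift in the pairing test, from -0.15 to -0.32 with 1-sided exact permutation p from 2.98e-04 to 0.00556 over the 6 SBC arrays, the Feature Extraction ratio, no filter, medians and each list left out. The 2-sided exact permutation p was the same except without the miR-34 5p targets, where it was 0.0149 against a 1-sided 0.00298. The number of shifted lists was 70 to 81, near the 78 first found. Of 312 list medians under other settings, relative to all genes, 246 stayed shifted with 1 sign, 52 moved inside the percentiles and 14 turned sign, so that 40 of the 78 shifted lists kept their call under all 4 other settings. Median centring turned DNA replication and G1/S to 0.0502 and unfolded protein stress to 0.0904 after miR-34c-3p. The Feature Extraction ratio turned ribosomal proteins to -0.0077 after miR-28-5p, and no filter turned urothelial markers to 6.52e-04 after miR-30a-3p. Subtraction of the other arrays of the line turned NF-kB to -0.0021 and hypoxia to 0.0107 after miR-30a-3p, epithelial markers to 0.0068 after miR-34b-3p, NF-kB to -0.0641 after miR-34c-5p, and DNA replication to 0.152 and unfolded protein stress to 8.36e-04 after miR-34c-3p. In T24 cells it turned miR-28-5p targets to 0.0018 after miR-28-5p, and ribosomal proteins to -7.72e-04, histones to -0.0044 and receptor tyrosine kinases to 0.0116 after miR-28-3p. Of 2910 values of genes named on single arrays, 1625 stayed within the spread used and 1285 moved beyond it.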

Other observations

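No hypothesis was tested in this part. Leukocyte markers were within the percentiles of random lists on all 8 arrays, and the fibroblast and endothelial list was outside only after miR-34c-5p (-0.18 over 4 measured genes).

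RN7SL1, the RNA of the signal recognition particle, differed from mock in either direction, at -1.69 after miR-30a-5p, -1.47 after miR-30a-3p, 0.54 after miR-34b-5p, 1.32 after miR-34b-3p, 0.16 after miR-34c-5p, -0.44 after miR-34c-3p, -0.31 after miR-28-5p and -0.94 after miR-28-3p. The short noncoding RNA SNAR-A3 was higher on all 6 SBC arrays, from 0.63 after miR-30a-3p to 1.92 after miR-34c-5p, and stood at 0.01 and 0.03 on the T24 arrays, a difference that was not tested.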
